A study of Escherichia coli with 8 samples.

How the data were processed

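Total RNA of biofilm and suspension cells of Escherichia coli K-12 BW25113 was hybridised to Affymetrix arrays with 7312 probe sets, with 1 array for each of 2 fractions at 4, 7, 15 and 24 h. Per the labels, cDNA was made by random priming, fragmented and end-labelled with biotin; the steps are spelled out for the biofilm 4 h sample and named only as the manufacturer's protocol for the other samples. The deposited values are intensity on a linear scale, MAS5 signals per probe set that the authors scaled so that the trimmed mean of each array is about the same. MAS5 is named for 7 of 8 samples without a version, and not for the suspension 24 h sample; detection calls, the scaling target and the culture replicates behind each array are not given in the sources used here. The 2% trimmed means of the 8 arrays lay between 500.1 and 500.2, within the limit of 1.2 times set for using the values with no further scaling.

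Probe sets were named by the locus tag in their own name, matched to a gene table of assembly ASM584v2, which gave 4183 gene probe sets, 1 per gene; 162 locus tags were not matched. A further 2886 intergenic, 59 foreign and 22 control probe sets were not tested. Probe sets were classed as foreign if their name held no single locus tag and was neither an intergenic nor a control name. The platform's own table pairs 1543 probe sets with 1 symbol, 2855 with several and 2914 with none. Assembly positions were not used. Some tRNA, ribosomal RNA and insertion sequence genes have several near-identical copies, and their probe sets cannot be assigned to a single copy.

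Signals below the median of all signals of all 8 arrays (261.7) were set to that floor, and log2 values were taken. The 2672 genes whose mean log2 signal before the floor was at or above the floor were tested. A fold against a signal at the floor is a lower bound and is written "at least".

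Models were fitted with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Biofilm minus suspension was fitted with time as a factor (3 residual degrees of freedom), so that its spread is that of the difference between the 4 times. The change over time was the moderated F test of the same fit. Slopes of log2 signal on log2 hours were fitted per fraction with a shared spread (4 residual degrees of freedom), with their difference as a further contrast. That spread is the departure from the straight lines, so a curved course over time widens it. All limma tests were two-sided. Each SE is limma's moderated one, which draws the spread of a gene toward that of all genes. The prior had 6.24 degrees of freedom for the difference and 4.29 for the slopes. At each single time, folds of at least 4 were counted without a test.

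A set of 46 gene lists, covering metabolism, transport, stress responses, cell surface structures and signalling, was tested by limma's camera with a preset correlation of 0.01, then with an estimated correlation and by fry. At each time the median of a list was placed among 10000 random lists of the same size matched on mean signal. Lists were fixed from general knowledge of the organism, without reference to these arrays. Of 960 list entries, 943 were on the array and 652 were tested.

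The genes named in the text were set by a rule. For the mean difference it took the 10 highest and 10 lowest mean differences of the same sign at all 4 times. For each time it took the 5 highest and 5 lowest folds with the higher signal at least 4 times the floor (1046.8). For trends it took the 5 steepest called slopes each way per fraction and the 5 largest slope differences each way. For each list it took up to 4 members. A set of 26 genes known from E. coli biofilm work was added.

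The fits were tested on simulated data with 2672 genes and the spread seen in the arrays. For the difference between fractions, 16.4% of genes changed by 0.5 log2 units, 89.6% of those changed by 1 and 100% of those changed by 2 were recovered, with 4 false calls. For the biofilm slope, recovery was 6%, 71.6% and 98.5% for slopes of 0.5, 1 and 2, with 2 false calls. For the change over time, it was 64.2%, 98.5% and 100% for a 2-, 4- and 8-fold change at 1 time, with 16 false calls. The simulated genes varied independently of each other. In each simulation 67, 67 and 66 genes were changed by the sizes given, which eases the adjusted threshold for all of them. The shares recovered therefore do not hold where few genes change, which was not simulated.

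Alternatives were the between-array scaling, the floor, the filter on dim genes, the variance model, the time scale, the set test, the fold threshold, and leaving out each time in turn. Alternatives chosen after the data were seen are named in the closing section. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.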

Results

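Transcript levels of Escherichia coli K-12 BW25113, the parent strain of a widely used collection of single-gene deletions, were measured in biofilm cells and in suspension cells of cultures grown in LB medium with glass wool for 4, 7, 15 or 24 h. Each of the 8 groups held 1 Affymetrix array with 7312 probe sets, so there were no replicates: p-values below measure the spread between times or between arrays, not between cultures. The number of arrays limits the precision of every value. The interquartile range of the log2 gene signals narrowed with time, from 2.29 at 4 h to 1.84, 1.71 and 1.09 at 7, 15 and 24 h in biofilm. In suspension it went from 2.37 to 2.29, 2.02 and 1.62. Of 7 genes deleted in this strain, 2 passed the filter on dim genes: araD, with signals up to 809.6, and rhaD, up to 477.8, against a floor of 261.7; whether these signals came from other transcripts was not tested. The labelling spike-in probe sets also differed between times: in each fraction their geometric mean signal at 7 and 15 h was at least 4.04 times that at 4 and 24 h.

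Most of the spread between the arrays lay between the times. The 2 fractions of a time correlated across genes at r of 0.932 to 0.965, while 4 and 24 h correlated at 0.712 in biofilm and 0.703 in suspension; genes are not independent replicates. A first principal component with 53.5% of the variance ordered the arrays by time, and a second with 21.3% parted 4 and 24 h from 7 and 15 h, the same parting as that of the spike-ins. Of 2672 genes tested, 1355 (50.7%) changed over the 4 times by limma's moderated F test. That test takes the 2 fractions of a time as its values for that time. Any difference between the cultures or array runs of the times therefore counts as change over time. With no filter on dim genes 654 did so, 738 without the 24 h arrays and 846 without the biofilm 24 h array.

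Averaging over the 4 times asks how attached cells differed from suspended cells of the same culture age. The largest mean differences of the same sign at all 4 times were 1.05 and -0.76 log2 units. Higher in biofilm at all 4 times were the leucine tRNA gene leuW, by 1.05 ± 0.25 (log2, moderated SE, n = 4 times), and hcaR, the regulator of phenylpropionate breakdown, by 0.77 ± 0.18. So were atoA, a subunit of the acetoacetate transferase, by 0.75 ± 0.29, mrcA, which encodes penicillin-binding protein 1A, by 0.69 ± 0.20, and feoC of the ferrous iron transporter, by 0.67 ± 0.20. Lower in biofilm at all 4 times were bsmA, a biofilm and stress lipoprotein gene, at -0.76 ± 0.26, fumA, a fumarase, at -0.70 ± 0.21, and pepT, peptidase T, at -0.69 ± 0.17. So were gltA, citrate synthase, at -0.66 ± 0.19, csrA, the carbon storage regulator, at -0.63 ± 0.19, and artI, an arginine-binding protein, at -0.62 ± 0.15. The main fimbrial subunit gene fimA differed more, by 1.43 ± 0.42, but was higher at 3 times only, with both fractions at the floor at 24 h. None of these passed the test: limma called 0 genes, with a smallest adjusted p of 0.617, and 211 genes at an unadjusted p under 0.05 against 134 by chance. The 4 and 24 h arrays alone gave 10 genes. A count of 0 from so few arrays does not show that the fractions were alike.

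Of 26 genes fixed for their known roles in E. coli biofilms, 23 were tested; 21 had a mean difference under 0.5 log2 units in size, and fimA and csrA a larger one. Differences were -0.49 ± 0.19 for the biofilm regulator bssR, -0.40 ± 0.14 for hns, a nucleoid protein, and -0.44 ± 0.17 for rbsB, the ribose-binding protein, each lower in biofilm at all 4 times. They were -0.04 ± 0.32 for bssS, 0.08 ± 0.16 for luxS, which makes autoinducer 2, 0.06 ± 0.15 for the curli subunit csgA, -0.02 ± 0.16 for flagellin fliC and -0.14 ± 0.19 for the stationary-phase sigma factor rpoS. They were -0.38 ± 0.30 for ariR, 0.31 ± 0.18 for gatB, -0.28 ± 0.53 for tnaA and 0.18 ± 0.16 for lsrB, the autoinducer 2 binding protein. The other 9, gatA, ymgA, tomB, hha, bhsA, rmf, ompF, ompC and crp, lay between -0.14 and 0.14. None was called, and the signs for bssS, luxS, csgA and rpoS turned under other between-array scalings. The curli regulator csgD, the adhesin gene flu and ymgC were too dim to be tested.

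Among 46 gene lists, 5 were called for the difference between fractions. Camera does not match lists on brightness, and the called lists lower in biofilm were the brighter ones. Their mean suspension signals were 10.3 to 11.3 log2 units, against 8.2 and 8.6 for those higher in biofilm. Among genes of a mean signal at least 2 times the floor, the median difference was -0.1. How far brightness accounts for these calls was not tested. All 15 tested genes of the tricarboxylic acid cycle had a lower mean in biofilm, with a median of -0.38. Examples besides fumA and gltA were acnB, aconitase, at -0.52 and sucD, succinyl-CoA synthetase, at -0.40. The list had an adjusted p of 1.1e-07, and an adjusted p = 0.75 with an estimated correlation. Its difference was largest at 4 h, with medians of -0.684, -0.234, -0.145 and -0.433 at 4, 7, 15 and 24 h. These lay at percentiles 0, 21.9, 37.6 and 8.8 of random lists matched on mean signal. After quantile normalization the medians at these times were -0.73, -0.07, -0.002 and -0.06, with a median of -0.25 over all times. In the general stress regulon of RpoS, 52 of 57 tested genes had a lower mean in biofilm, with a median of -0.28 (adjusted p = 2.25e-09, and adjusted p = 0.612 with an estimated correlation). Examples were yahO at -0.67, the aminotransferase gene gabT at -0.67 and the lipoprotein gene osmE at -0.65. After quantile normalization the median was -0.16 (adjusted p = 0.0245), and that at 24 h turned from -0.38 to 0.04. All 18 tested genes of aerobic respiration had a lower mean in biofilm, with a median of -0.23 (adjusted p = 0.00312, and adjusted p = 0.812 with an estimated correlation). Among them were cyoD of cytochrome bo oxidase at -0.59 and nuoH of NADH dehydrogenase I at -0.42. Without the suspension 4 h array the adjusted p of that list was 0.717, and its median was 0.02 on the 7 and 15 h arrays alone. All 9 tested genes of methionine synthesis and uptake had a higher mean in biofilm, with a median of 0.28 (adjusted p = 0.00263, and adjusted p = 0.612 with an estimated correlation). Examples were metK at 0.43, metQ at 0.39 and metH at 0.35. The median of methionine synthesis was 0.03 with arrays scaled to a common median, which moved the median difference of all genes to -0.24. The 3 tested genes of type 1 fimbriae, fimA, fimH (0.47) and fimE (0.44), had a higher mean in biofilm (median 0.47, adjusted p = 0.00523, and adjusted p = 0.612 with an estimated correlation). The call of methionine synthesis ended on the 4 and 24 h arrays alone (adjusted p = 0.112). That of type 1 fimbriae ended on the 7 and 15 h arrays alone (adjusted p = 0.296) or without the filter on dim genes (adjusted p = 0.107). That of aerobic respiration ended without the time factor (adjusted p = 0.12). With a mean signal of at least 2 times the floor, the adjusted p was 0.0767 for methionine synthesis and 0.0828 for aerobic respiration. Among random lists matched on mean signal, the RpoS medians at 4, 7, 15 and 24 h lay at percentiles 1.4, 0, 6.4 and 5.5. Those of aerobic respiration lay at 0, 98.1, 64.8 and 65.8. For methionine synthesis the percentiles were 93.4, 99.3, 89.8 and 63.9, and for type 1 fimbriae 99.6, 98, 75.3 and 99.9. Adjusted over the list alone, 3 genes of the tricarboxylic acid cycle and 2 of type 1 fimbriae were called, and 0 of the other 3 lists. Over all genes tested, 0 were called. Each other split of the 8 arrays that parts the fractions at all 4 times called 6 to 10 lists, more than these 5. The number of lists called therefore does not set the real grouping apart.

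The fractions were farthest apart at 4 h, where 19 genes differed by at least 4-fold, 9 of them higher and 10 lower in biofilm; 4 did with a mean signal of at least 2 times the floor. The tryptophan synthesis genes trpL, the leader, and trpE were at least 11-fold and 4.3-fold higher in biofilm, with a trpL signal of 2882.5 against a suspension signal under the floor. The tryptophan permease gene mtr was 5.1-fold higher. The superoxide regulator soxS was at least 11.8-fold higher, and the cold shock genes ynaE and cspI at least 11.9-fold and 5.35-fold higher. Suspension cells instead had 6.54 times the signal of tnaA, the tryptophanase that makes indole (26160.2 against 4000), and 6.09 times that of the tryptophan transporter gene tnaB; after quantile normalization the log2 difference of tnaA was -4.46. They also had 8.43 times the signal of the maltose-binding protein gene malE, 5.13 times that of the maltoporin gene lamB and 4.72 times that of malG. By list, the median log2 difference was 1.62 for tryptophan synthesis and 0.73 for acid resistance, both at the 100th percentile of random lists of equal brightness. It was -1.69 for maltose uptake, -1.52 for indole and tryptophanase, -0.77 for aerobic respiration, -0.68 for the tricarboxylic acid cycle and -0.49 for porins, all 5 at percentile 0. The indole list held members that went both ways, with tnaA, tnaB and tnaC lower and mtr and bhsA higher in biofilm, as did porins, with 10 of 13 lower. The suspension 4 h array alone carried signal on the TrpnX control probe sets, with a median of 3567.7, beside these tryptophan, maltose and respiration values.

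At the later times fewer genes stood apart, with at least 4-fold differences for 1 gene at 7 h, 1 at 15 h and 2 at 24 h. With no floor these counts were 2, 10 and 8, and without tRNA and rRNA genes none was left at 24 h. At 7 h fimA was at least 8.81-fold higher in biofilm, tnaA 3.02-fold higher, the reverse of its 4 h difference, and osmC, an envelope peroxidase gene, 2.88-fold higher. Suspension cells had 2.94 times the signal of osmE, 2.86 times that of cspE and 2.84 times that of ariR (also named ymgB), a regulator of biofilm and acid resistance genes. The RpoS regulon had a median of -0.38 at 7 h (percentile 0) and methionine synthesis one of 0.41 (percentile 99.3). After quantile normalization these were -0.27 and 0.22. With arrays scaled to a common median, which moved the median of all genes at 7 h to -0.27, they were -0.67 and 0.12. At 15 h the uncharacterised gene ycaR was at least 6.86 times higher in suspension and nlpI, a lipoprotein gene, 2.36 times, while the tRNA gene aspV was 3.75-fold and the 23S ribosomal RNA gene rrlE 3.14-fold higher in biofilm, though after quantile normalization the log2 difference of rrlE was 0.26. At 24 h the tRNA genes alaW and hisR had 4.82 and 4.09 times the signal in suspension, and type 1 fimbriae had a median of 0.92 (percentile 99.9). Only 3 of the 9 fimbrial genes were tested. At 24 h fimA was at the floor in both fractions, so that median rests on fimH and fimE alone. Over all 4 times, 38 of 184 medians lay outside the central 95% of random lists, 18 of them at 4 h; members of a list vary together, so the number that chance would give is not known. A time holds 1 array per fraction, so no difference at a single time was tested.

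**Figure D1:**
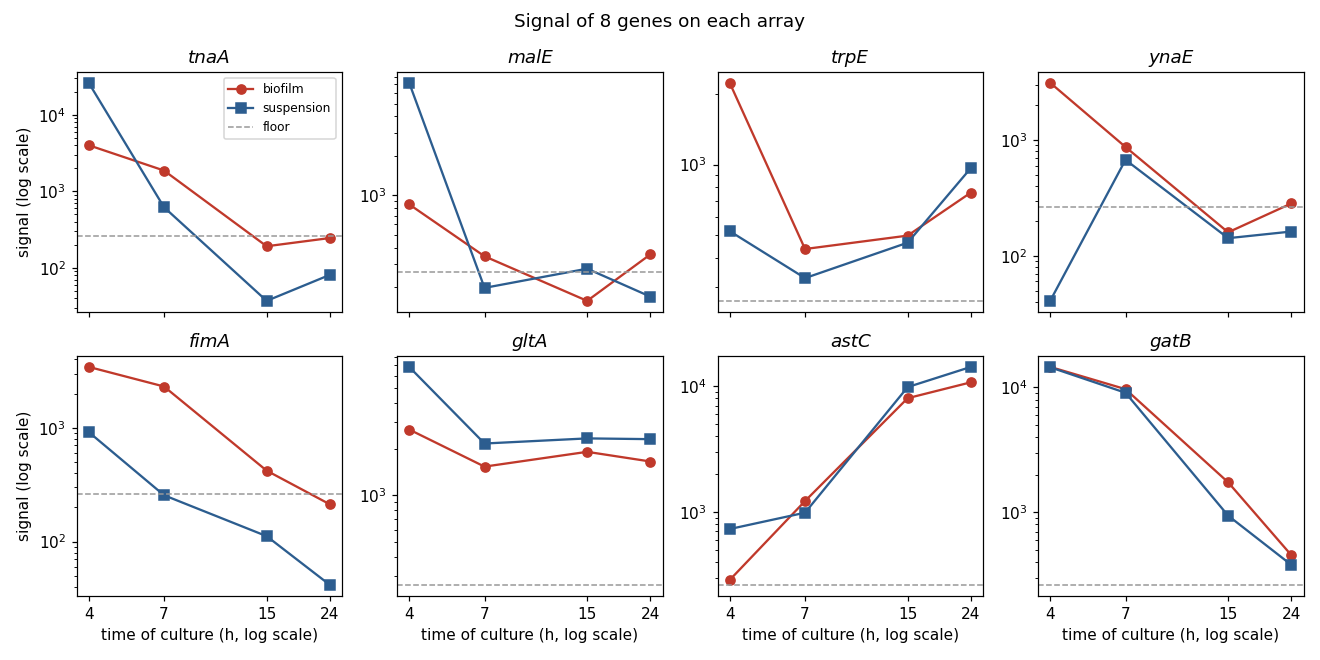
MAS5 signal (log axis) against hours of culture (log axis) for 8 named genes, with 1 point per array and a line per fraction. The tryptophanase gene tnaA starts at 26160.2 in suspension and 4000 in biofilm, and fimA is higher in biofilm at 4, 7 and 15 h.

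**Figure D2:**
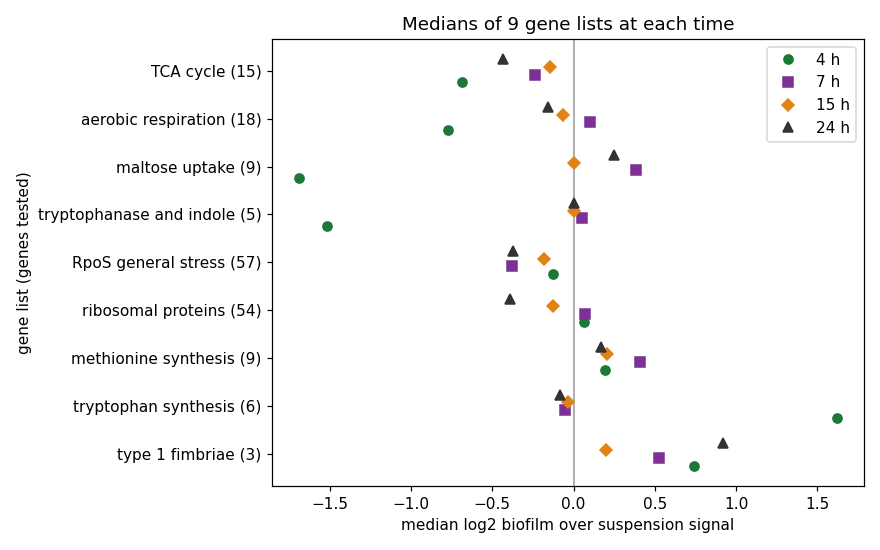
Median log2 difference of biofilm over suspension for 9 gene lists at 4, 7, 15 and 24 h, with 1 value per list and time from a single pair of arrays. The widest values are at 4 h, from -1.69 for maltose uptake to 1.62 for tryptophan synthesis.

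Over time in biofilm, 4 genes of arginine breakdown and the fatty acid oxidation gene fadE rose, while single genes for galactitol uptake, peptide uptake, fimbriae and nucleotide balance fell. The arginine succinyltransferase pathway genes astC, astA, astD and astB rose by 2.10 ± 0.25, 1.48 ± 0.19, 1.38 ± 0.21 and 1.24 ± 0.17 log2 units per doubling of hours (moderated SE, 4 arrays). The acyl-CoA dehydrogenase gene fadE rose by 1.12 ± 0.17. Falling slopes were -1.98 ± 0.24 for the galactitol transporter gene gatB, -1.86 ± 0.27 for the oligopeptide-binding protein gene oppA, -1.56 ± 0.24 for fimA and -0.96 ± 0.13 for the adenylate kinase gene adk. The adjusted p was 0.0341 for astC, astA, gatB and adk, 0.0429 for astB, and 0.0477 for astD, fadE, oppA and fimA. These 5 rising and 4 falling genes were all that limma called, with 604 genes at an unadjusted p under 0.05. The SE and p-values of slopes measure the departure from a straight line, so a gene with a curved course could change without being called. No gene was called without the 15 h arrays, the 24 h arrays or the biofilm 24 h array, or with time as a rank. Without the filter on dim genes 2 genes were called, and 324 with the split shown by the spike-ins as a term. With arrays scaled to a common median, which moved the median slope of all genes to -0.21, 7 genes rose and 238 fell.

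In suspension, the reference for the biofilm time course, 29 genes rose and 61 fell. All 5 genes that rose in biofilm rose here too, as did the superoxide dismutase gene sodA, by 1.35 ± 0.26 per doubling (adjusted p = 0.0351). Among those that fell were tnaA, with a slope of -2.39 ± 0.52 (adjusted p = 0.0497; from 26160.2 at 4 h to under the floor at 15 and 24 h). Others were gatB, at -2.17 ± 0.24 (adjusted p = 0.0166), gatD, at -2.14 ± 0.35 (adjusted p = 0.0266), and ompW, an outer membrane protein gene, at -2.07 ± 0.33 (adjusted p = 0.0239). Of the 4 genes that fell in biofilm, 3 also fell in suspension; fimA had a suspension slope of -0.61 ± 0.24 (adjusted p = 0.175). The suspension count was 0 without the 15 h arrays, without the 24 h arrays or without the suspension 4 h array. It was 1 without the filter on dim genes, and 402 with the spike-in split as a term. With arrays scaled to a common median, which moved the median suspension slope of all genes to -0.16, 19 genes rose and 234 fell.

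Of the 46 lists, 19 were called for a trend in biofilm, against 0 with an estimated correlation and 5 by fry. The 5 by fry, each at adjusted p = 0.0493, were adhesins, fatty acid oxidation, the tricarboxylic acid cycle, pyrimidine synthesis and the deleted genes. Camera did not call pyrimidine synthesis or the deleted genes (adjusted p = 0.0625 for each). Of the 9 called lists first named below, fry called only fatty acid oxidation and the tricarboxylic acid cycle. All 54 ribosomal protein genes had falling slopes (median -0.47, adjusted p = 1.06e-13), as did all 9 of ATP synthase (median -0.84, adjusted p = 2.13e-06) and all 6 of galactitol uptake (median -1.84, adjusted p = 4.48e-06). Falling slopes were also found for 17 of 18 tested genes of aerobic respiration (median -0.62, adjusted p = 4.12e-10), 13 of 15 of the tricarboxylic acid cycle (median -0.55, adjusted p = 0.000295) and 11 of 13 tested porin and outer membrane genes (median -0.58, adjusted p = 0.000542, and 0.0507 without the 4 h arrays). Slopes were positive for all 22 tested of 52 flagellar and chemotaxis genes (median 0.34, adjusted p = 0.00016, and 0.298 among genes of a mean signal at least 2 times the floor), 8 of 9 of fatty acid oxidation (median 0.63, adjusted p = 0.00016) and all 15 tested of 28 phosphate starvation genes on the array (median 0.29, adjusted p = 0.00136, and 0.32 without the 4 h arrays). Beside these rising lists, araD and rhaD, both listed as deleted in this strain, had a median slope of 0.48 (camera adjusted p = 0.0625, and adjusted p = 0.439 with an estimated correlation; fry adjusted p = 0.0493). In suspension the median slopes of the 9 called lists named here had the same sign as in biofilm. They were -0.24 for ribosomal proteins, -0.90 for ATP synthase, -2.01 for galactitol uptake, -0.85 for aerobic respiration and -0.51 for the tricarboxylic acid cycle. For porins the value was -0.79, and for flagella, fatty acid oxidation and phosphate starvation 0.35, 0.33 and 0.23. No list was tested for a trend in suspension. For each of these 9 lists the adjusted p for biofilm was 0.439 with an estimated correlation. Adjusted over the list alone, 21 ribosomal protein genes, 14 of aerobic respiration, 7 of ATP synthase, 7 of fatty acid oxidation and 7 porin genes were called. So were 6 of the tricarboxylic acid cycle, 5 of galactitol uptake, 1 flagellar and 1 phosphate starvation gene, against 1 gene each of galactitol uptake and fatty acid oxidation, and 0 of the other 7 lists, over all genes. For acid resistance 14 of 15 tested genes had falling slopes (median -0.77, adjusted p = 0.000659, and adjusted p = 0.439 with an estimated correlation), but the adjusted p was 0.0514 with arrays scaled to a common median. The median slope of acid resistance was 0.06 without the biofilm 24 h array, the array with the narrowest range of signals, with an adjusted p of 0.443.

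Whether the difference between the fractions moved with time was asked by comparing the slopes. The slope of the maltose genes malE, malG and lamB was higher in biofilm by 1.11 ± 0.71, 0.99 and 0.91 per doubling, and that of soxS, ynaE and trpL lower, at -1.26 ± 0.65, -1.21 ± 0.40 and -1.05 ± 0.72; all 6 differed by at least 4-fold at 4 h. For fimA it was -0.95 ± 0.34. None passed the test: limma called 0 genes, with 23 at an unadjusted p under 0.05 against 134 by chance. The spread of this fit is the departure from straight lines, so a curved course shared by both fractions widens it. With time as a factor, which takes out a shared course, 0 genes were called too. A count of 0 from so few arrays does not show that the difference stayed the same over time. Across genes the slopes of the fractions correlated at r = 0.849, and 81.9% had the same sign.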

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

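The tests of the signal range and of the spike-in split, the bound that excludes background (first 0.25 and then 0.75 of the rise of the dim probe sets), and the counting of splits by distinct fits, were chosen after the results were seen; the growth phase test and the count of splits for genes past the adjusted threshold were set before the data were examined, and the other counts of splits later but before they were made.

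Control probe sets outside the gene comparisons carried signals that followed the times. The geometric mean of the 12 DapX, LysX, PheX and ThrX spike-in probe sets was at least 4.65 times higher at 7 and 15 h than at 4 and 24 h in biofilm, and at least 4.04 times higher in suspension. The TrpnX control probe sets had a median signal of 3567.7 on the suspension 4 h array alone.

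The spike-in split, weighed as an array processing batch, falls where the second principal component does. With the split as a term in the trend fits, 324 genes had a called slope in biofilm in place of 9. The split is nearly uncorrelated with log2 hours (r = -0.03), so the term could not have taken the slopes away and this count decides nothing about a batch. On the contrast of 4 and 24 h with 7 and 15 h, 489 genes were called. Each time lies on 1 side of the split, so for these genes a processing batch cannot be told apart from a curved course over time, which is the biological reading the design gives.

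The signal range of the arrays narrowed from 4 to 24 h, most in biofilm. In biofilm the 25th percentile of all probe sets rose by 1.54 log2 units and the median of the 59 foreign probe sets by 0.22 (95% bootstrap interval -0.81 to 0.74); in suspension these were 1.1 and 0.5 (-0.1 to 0.89). Unspecific background on all probe sets would need a foreign rise of at least 1.16 in biofilm, which lies above its interval. The 0.83 it would need in suspension lies inside the interval, so it stays open there. In biofilm the foreign probe sets argue against it as the whole cause, but the 7 genes deleted in this strain do not. Their quartiles in biofilm, 0.71 and 2.21, lie on either side of 1.16, so background is not settled there either. The foreign medians of the arrays, 20.7 to 43.7, also lay at the low end of the signals. Signal from chromosomal RNA or DNA at every locus stays open too: the 7 genes deleted in this strain rose by a median of 1.11 in biofilm (quartiles 0.71 and 2.21) and 1.15 in suspension (-0.31 and 1.42), too few and too spread to decide. The median of the intergenic probe sets rose by 1.25 in biofilm and 1 in suspension. They are 2886 of the 7312 probe sets that set the 25th percentile, so their rise is part of the pattern and does not decide its cause. A biological flattening of the transcript levels in old cultures was not tested.

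A shift in growth phase between the fractions might account for the differences at a time. If it did, the difference at each time would follow the change of suspension cells between other times across genes. The r across genes was 0.017, -0.007, 0.079 and -0.117 at 4, 7, 15 and 24 h, nearest to 0 at 7 h, with signs that differed between times. At 7 and 15 h, this argues against a shift along the suspension change from 4 to 24 h as the whole cause. The test says nothing of a shift the other times do not contain. At 4 and 24 h the change used left out the step next to that time, so a shift stays open there. Suspension medians at 7 minus 4 h were near the 4 h difference for the tricarboxylic acid cycle (-0.688 and -0.684). So were those for maltose uptake (-1.851 and -1.688), but not those for tryptophan synthesis (-0.265 and 1.618). Both values of a pair share the suspension 4 h array. A difference between attached and suspended cells stays open as the biological explanation and was not tested further.

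In 14 genes the difference between fractions was at least 2-fold in opposite directions at different times, among them tnaA, cspA and bssS. The comparison of slopes called 0 genes, and a change of the difference between single times was not tested.

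Other splits of the 8 arrays into 4 and 4 were counted for the difference between fractions. Of 35 splits, 3 could not be fitted with time as a factor, and the 32 others gave 20 distinct fits, too few for a share under 0.05. For genes past the adjusted threshold, all 20 fits gave at least the real count of 0, the highest other being 2. For genes at an unadjusted p under 0.05, the real split gave 211 and the highest other 197, 1 fit reaching the real count; counted over the 32 fitted splits, as was first done, this would have been 1 of 32. For lists called, the real split gave 5 and the highest other 17, with 15 of the 20 fits reaching the real count. Most of these fits part the fractions at 2 of the 4 times only. Among the 8 that part them at all 4 times, as the real one does, the highest other was 1 gene past the adjusted threshold and 197 at an unadjusted p under 0.05. The 7 others gave 6 to 10 lists, each more than the 5 of the real split. The split that follows the spike-ins is among the 3 that could not be fitted.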

How the results depend on the processing

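The spike-in term, the fits to 4 and 24 h or 7 and 15 h alone, those without the biofilm 24 h or suspension 4 h array and those without tRNA and rRNA genes were chosen after the data were seen. The signal over the floor limits what can be compared: 2672 of 4183 genes passed the filter, among them 2 of the 7 genes deleted in this strain, so passing it does not show that a gene was expressed. Slope differences gave 0 genes under every alternative run. Of 882 mean differences of named genes under alternatives, 820 kept their sign and side of the threshold, 58 changed sign without being called and 4 came to pass; of 265 folds at a time, 257 stayed within 1.5 times and 8 moved further. Where not explained by fewer genes or arrays, the cause was not tested. Quantile normalization gave 114 genes with a biofilm trend (53 rising, 61 falling) and 4 genes at least 4-fold apart at 24 h. Scaling to a common median gave 245 biofilm trends (7 rising, 238 falling), 253 suspension trends (19 and 234) and 10 lists. It moved the median slope of all genes to -0.209 in biofilm and -0.155 in suspension, and the median difference to -0.24. The median of cyclic di-GMP enzymes (-0.119) and the slopes of fermentation (-0.062), nitrogen limitation (-0.074) and the RpoS regulon (-0.073) turned negative with that shift, all 4 still above the median of all genes. No floor gave 1 gene for the difference between fractions and 2, 10 and 8 genes at least 4-fold apart at 7, 15 and 24 h; the lower floor gave 2 and 4 at 15 and 24 h. No filter gave 654 genes changing over time, 2 biofilm and 1 suspension trends and 9 lists. A mean of 2 times the floor gave 845 over time, 4 and 0 genes 4-fold apart at 4 and 7 h, and 3 lists. The trend and robust variance model gave 23 biofilm trends, and time as a rank 0 and 9 in suspension. The estimated correlation gave 0 lists for the difference and 0 for the trend, and fry 0 and 5. At 2-fold, 155, 54, 54 and 40 genes differed at 4, 7, 15 and 24 h. Leaving out each time gave 738 to 1123 genes over time, 0 to 12 biofilm trends, 0 to 69 suspension trends, and 5 to 10 and 14 to 20 lists; the acid resistance slope ran from -1.215 to 0.055 (0.055 also without the biofilm 24 h array) and the iron uptake slope from -0.189 without 4 h to 0.744. The spike-in term gave 324 and 402 trends. The 4 and 24 h arrays alone gave 10 genes, 14 lists and reversed medians for cold shock (0.118), glyoxylate (-0.11) and indole (-0.878); the 7 and 15 h arrays gave 3 lists and 0.018 for aerobic respiration. Without the biofilm 24 h array 846 genes changed over time, with 0 biofilm and 36 suspension trends; without the suspension 4 h array the trends were 25 and 0. Without tRNA and rRNA genes, 0 genes were 4-fold apart at 24 h.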

Other observations

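The grouping of genes by RNA class was chosen after the values were seen, and none of its values was tested. Stable RNA differed between the fractions in a way that turned with time. All 18 ribosomal RNA genes had a higher signal in biofilm at 4, 7 and 15 h, with median log2 differences of 0.23, 0.72 and 1.34, and all 18 a lower one at 24 h, with a median of -0.63; their probe sets read near-identical copies and are not independent. After quantile normalization these medians were 0.01, 0.02, 0.02 and 0. That scaling gives genes of equal rank equal values, so it takes out any difference of genes that keep their rank. The values after it cannot tell whether the difference came from scaling. Of 64 tRNA genes, 50 were higher in biofilm at 4 h and 61 at 15 h, with medians of 0.66 and 0.64. At 7 h 31 were higher and 32 lower, with a median of -0.03, and 57 were lower at 24 h, with a median of -0.53. The median of the other genes was within 0.03 log2 units of 0 at 24 h.

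Insertion sequence genes, mobile elements present in several copies, had a median of 0.58 at 24 h, with 16 of 18 higher in biofilm; it was 0.25 with arrays scaled to a common median and 0.90 after quantile normalization.

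Heat shock and envelope stress genes had medians of 0.23 and 0.35 at 4 h, at percentiles 99.4 and 99.9 of random lists of equal brightness. At 24 h the medians were 0.30 for galactitol uptake (percentile 100) and 0.36 for branched-chain amino acid synthesis (percentile 99). With arrays scaled to a common median, which moved the median of all genes at 24 h to -0.33, they were 0.00 and 0.03. From 4 to 24 h the galactitol genes changed by medians of -4.272 log2 units in biofilm and -4.691 in suspension. Their random lists were matched on the mean over all arrays, so that percentile does not compare genes of equal signal at 24 h.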
